A study of Mus musculus with 4 samples.

How the data were processed

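Gene expression was measured in mouse bone marrow cells cultured with macrophage colony-stimulating factor (M-CSF), the growth factor that drives marrow progenitors towards macrophages. Per the labels' protocols, marrow of 21 C57BL/6 mice was pooled, red cells were lysed, and the cells were sealed with 1.5 µg/ml M-CSF in glass barrels with separate fluid chambers. Some barrels flew on a space shuttle and parallel barrels stayed on the ground under the same temperature profile at 37 °C. Medium was added on culture day 6, and the cells were lysed in guanidinium on culture day 15, which was spaceflight day 14. RNA of 2 barrels was combined per sample, giving 4 RNA pools per group, and the best 2 of each group by RNA quality were put on arrays. The labels give an RNA integrity number of 3 for each of them, with 21.2 and 25 ng of RNA for the space flight pools and 12.5 and 24.1 ng for the ground control pools. The same protocol says that 50 ng of RNA was primed, and which amount is right could not be settled. The labels name these pools by letters that could not be matched to the replicate numbers. RNA went through 2 rounds of amplification and biotin labelling and was hybridised to Affymetrix mouse whole-genome arrays, which place several oligonucleotide probes per transcript near its 3' end.

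The deposited table holds 1 intensity per probe set and array on a linear scale, for 45101 probe sets, 64 of them controls. The software named in the submitters' processing notes is GCOS, with its version not stated; the summarising algorithm and scaling target are not given in the sources used here. As the deposited intensity values show, the mean after trimming 2% from each end was 500.004 on each of the 4 arrays, so each array had been scaled by 1 factor. Precision is limited by the number of arrays.

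From these intensities, log2(value + 16) was computed in R 4.3.3. A fold change on this scale understates the change of dim genes. The largest difference between array medians was 0.385 on the log2 scale, above the tolerance of 0.1 set in advance, so the arrays were quantile normalized without the control probe sets. Of the 45037 other probe sets, 34945 had 1 gene symbol in the platform annotation, 932 had several, and 9160 were unnamed here. Through gene identifiers, 34741 of the single symbols were found in a RefSeq gene table of assembly GRCm38.p6, used for names alone, and 0 symbols changed. No gene was named from a probe set with several symbols. The sources used here name no genome build for the probe sets, so no positions are given. Each of the 18193 genes was represented by its brightest single-gene probe set. The 11141 genes whose mean reached 6.40, the median over the 45037 probe sets, are called measured genes.

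Space flight was compared with ground control in limma 3.58.1 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values for genes come from this limma test. Residual degrees of freedom were 2, and the moderated test had 10.4. An exact test of 2 against 2 arrays cannot give a two-sided p below 0.333. The replicates are separate culture pools made from 1 pool of marrow, so the p-values cover spread between cultures and arrays, not between animals. Errors of log2 differences are standard errors from limma; those of group means are SDs of 2 arrays.

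Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives except where stated. There were 35 lists, 22 of biology and 13 of cell types, with 832 genes in all, of which 622 were measured. The 34 lists with at least 5 measured genes were tested with limma's camera, which asks whether a list stands apart from the other measured genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera was repeated with the correlation estimated per list, which had little power with 2 residual degrees of freedom. In addition fry was run, which asks whether the genes of a list move on balance 1 way without setting them against other genes. Named genes were the 12 highest and 12 lowest measured genes past the threshold whose space flight values both lay outside the ground control range, topped up to 12 by smallest p as values only; 10 genes of the study's subject; 4 members of each called list with the largest moderated statistic in the direction of the call; the 2 brightest members of each cell type list; and control probe sets of Gapdh, Actb and the transferrin receptor. These gave 92 genes. For 12 of them probe sets bright enough to be measured pointed in opposite directions: Arsb, Cep85, Cpt1a, Fabp4, H2-Aa, Id2, Itgb3, Lcp1, Scd2, Sdc1, Spn and Xist.

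Simulated data had the observed gene means and limma's moderated SDs, so they were built on the model of the test itself. The procedure was tested on these data, with 11141 genes independent of each other and 200 of them changed. For the comparison of space flight with ground control it recovered 36 of 100 genes changed by 1 log2 unit and 83 of 100 changed by 2, called 11 unchanged genes, and called 0 genes and 0 lists when nothing was changed. Because simulated genes were independent, this cannot show how often lists whose members vary together are called falsely. The alternatives were the deposited scaling, cyclic loess, a shift to 1 median, pseudocounts of 1 and 64, no filter on dim genes, a filter at the 75th percentile, the mean of a gene's probe sets, each probe set on its own, eBayes without a trend or with robust variances, a replicate block, each array left out in turn, other thresholds, and the other list tests.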

Results

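The study asked how macrophages differentiate from bone marrow cells in culture during space flight. Transcript levels were measured on 4 arrays, 2 of mouse bone marrow cultures flown on a space shuttle and 2 of parallel cultures kept on the ground. All cultures came from 1 pool of marrow and were lysed on culture day 15 in M-CSF, and each array held RNA of a separate pool of 2 culture barrels. Values are quantile normalized log2 intensities, and differences are space flight minus ground control. The RNA was degraded on all arrays by its integrity number of 3, and the arrays were not alike. The ratio of 3' to 5' signal of the Gapdh control was 4.09 and 15.2 on space flight arrays 1 and 2, against 4.13 and 3.33 on ground control arrays 1 and 2. For Actb these ratios were 3.08, 4.91, 2.30 and 2.84, and for the transferrin receptor 5.50, 3.47, 4.96 and 7.84. Across genes, the SD of the difference between replicates was 0.70 for space flight and 0.47 for ground control.

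**Figure D1:**
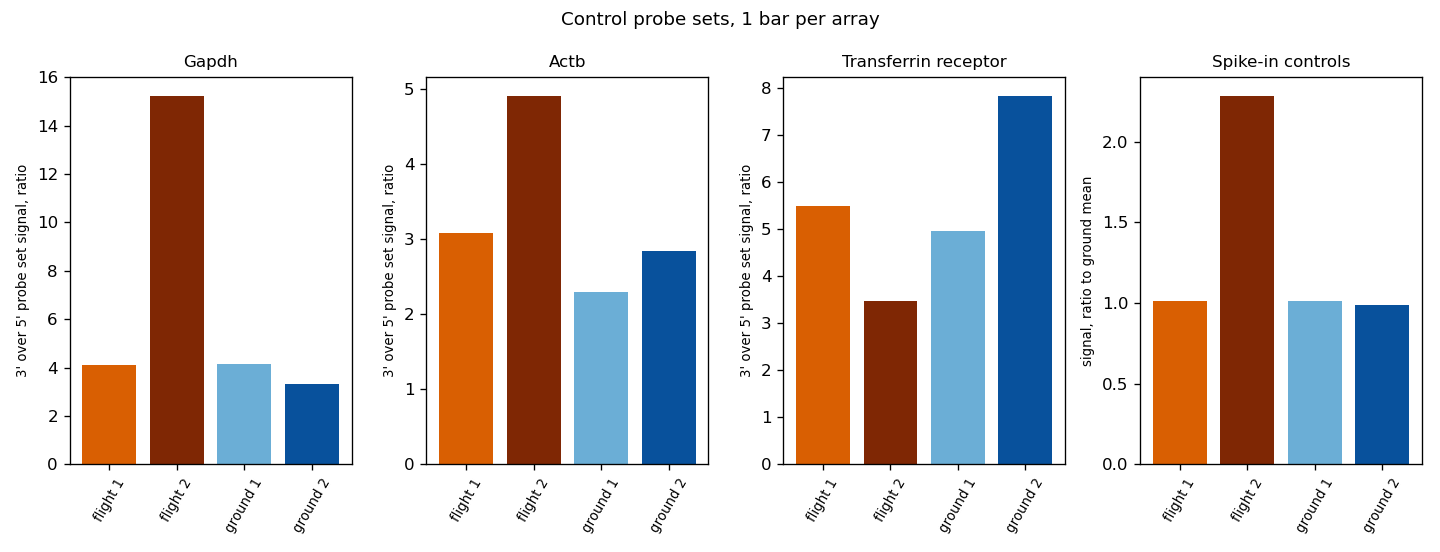
Bars give the ratio of 3' to 5' probe set signal of 3 control genes and the spike-in signal relative to the ground control mean, 1 bar per array, each panel with its own axis from 0. Space flight array 2 has the highest Gapdh ratio, 15.2, and the highest spike-in signal, 2.29, but the lowest transferrin receptor ratio, 3.47.

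In the cultures lysed in flight, the neutrophil granule genes Camp and Ngp rose 3.91-fold and 2.86-fold over the ground cultures, by 1.97 ± 0.26 and 1.51 ± 0.20 on the log2 scale (SE, n = 2 arrays per group). Odc1, the rate-limiting enzyme of polyamine synthesis, rose by 1.54 ± 0.18 (SE), and the insulin-like growth factor gene Igf1 fell by 1.80 on the log2 scale (SE 0.19). As a list, neutrophil and granulocyte markers stood highest of the gene lists tested, with a median difference of 1.36 over 17 genes (camera adjusted p = 1.47e-11; adjusted p = 0.628 with an estimated correlation). The receptor for M-CSF, Csf1r, had a difference of −0.37 ± 0.11 (SE) on its brightest probe set that did not pass the test (limma adjusted p = 0.181), and −1.20 and −0.95 on its 2 other probe sets.

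Of 11141 measured genes, 5 rose and 2 fell at the threshold. Camp, an antimicrobial peptide of neutrophil secondary granules, had 13.48 ± 0.56 in space flight and 11.51 ± 0.15 in ground control (SD, n = 2; limma adjusted p = 0.0347). Ngp, a neutrophil granule protein, had 13.57 ± 0.28 and 12.05 ± 0.12 (SD, n = 2; limma adjusted p = 0.0347). Odc1 had 13.59 ± 0.089 and 12.05 ± 0.032 (SD, n = 2; limma adjusted p = 0.0218). Its probe set is of the maker's class that can also bind other transcripts, and its 2 other probe sets gave 1.73 and 1.32. The centrosomal gene Cep85 had a difference of 2.38 ± 0.28 (SE; adjusted p = 0.0218), but its other, dimmer probe set gave −0.11. The histone gene H3c11 had the largest difference of the 7, 3.83 ± 0.53 (SE; adjusted p = 0.0370). Its ground control mean of 5.56 lay below the dim limit of 6.40, and histone genes of this family are near-identical copies that a probe set may not separate. Igf1 had 11.64 ± 0.005 in space flight and 13.44 ± 0.14 in ground control (SD, n = 2; limma adjusted p = 0.0218), and its 3 other probe sets gave −1.47, −2.59 and −1.45. Mamdc2 fell by 1.84 (SE 0.25; adjusted p = 0.0347). With 1 array left out, the lone array is assumed to vary like the other group, and the counts of higher and lower genes were 470 and 610 without space flight replicate 1, 342 and 399 without space flight replicate 2, 6 and 1 without ground control replicate 1 and 31 and 10 without ground control replicate 2. Each of the 7 differences kept its sign there, and that of Mamdc2 ran from −2.01 to −1.66. The moderated test then had 28.2 to 33.1 degrees of freedom, against 10.4 with all arrays. Because the 7 genes had also been chosen on these arrays, these fits were no independent check of them.

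At an adjusted p under 0.10 there were 53 higher and 47 lower genes, and at an unadjusted p under 0.05 there were 767 and 815, or 14.2% of measured genes where chance gives 5%. Both space flight values lay above, or both below, the 2 ground control values for 5069 genes, 45.5% where chance gives 33.3%. Other splits of the 4 arrays were not counted. Genes that vary together can move both shares away from these chance values, so neither shows an excess due to space flight. Among the genes next in rank, which did not pass, were Bbc3 at 2.39 ± 0.36 (SE), a cell death gene induced by p53, the antiprotease Slpi at 1.66 ± 0.26, the granule genes Ltf at 1.68 ± 0.27 and S100a8 at 0.79 ± 0.12, the NF-kB regulator Nfkbiz at 1.64 ± 0.27, the respiratory complex I subunit Ndufa5 at 1.14 ± 0.19, and 2410006H16Rik at 1.51 ± 0.25. Below 0 in the same rank were Gask1b at −1.92 ± 0.29, Col18a1 at −1.84 ± 0.32, Arsb at −1.57 ± 0.26, Xist at −1.28 ± 0.19, Ctso at −1.17 ± 0.21, the acid ceramidase gene Asah1 at −1.09 ± 0.17, the Fc receptor gene Fcgr3 at −1.02 ± 0.18, Csf2rb at −1.00 ± 0.15, Csf2rb2 at −0.93 ± 0.15 and the phagosomal metal transporter Slc11a1 at −0.89 ± 0.15. Adjusted p of these 17 genes ran from 0.0501 to 0.0676. Csf2rb and Csf2rb2 are near-identical copies. Other measured probe sets gave 0.41 and −0.53 for Arsb, −0.16 and 0.49 for Xist and −0.29 for Col18a1.

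**Figure D2:**
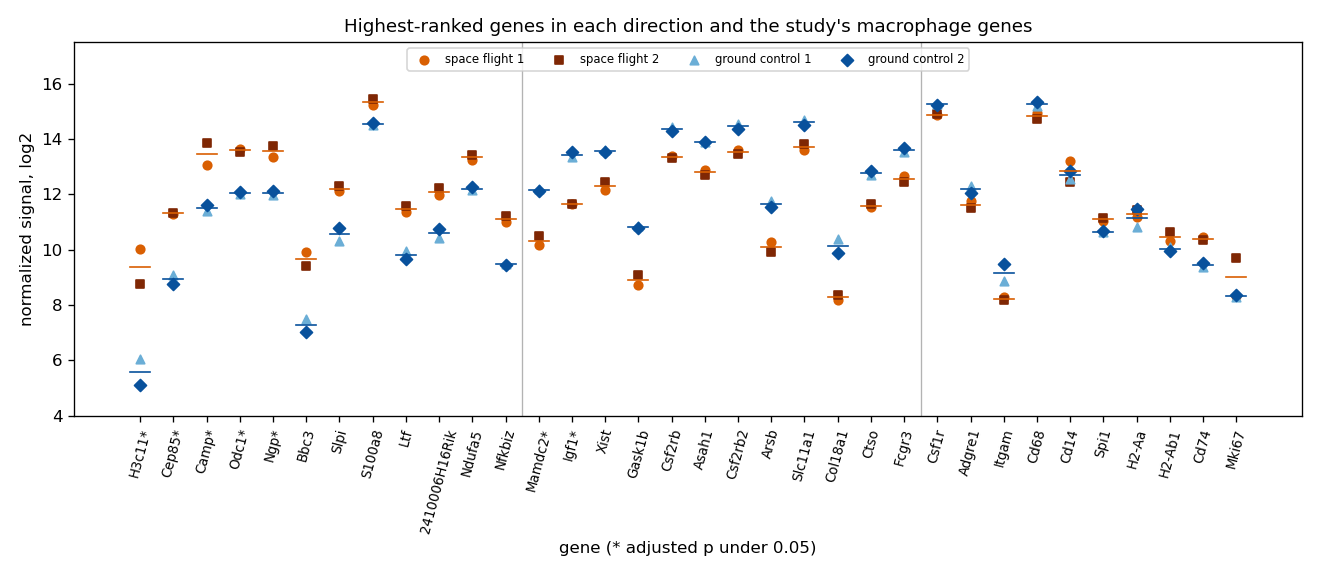
Points give the normalized log2 signal of each of the 4 arrays for the 12 genes of highest rank in each direction and 10 genes of the study's subject, with lines at the group means. Stars mark the 7 genes past the threshold; Odc1 lies at 13.59 in space flight and 12.05 in ground control, while the values of Cd14 and H2-Aa overlap between groups.

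None of the 10 genes named for the study's subject passed the test. The macrophage genes Cd68, Adgre1 and Itgam had differences of −0.43 ± 0.13, −0.56 ± 0.22 and −0.93 ± 0.34 (SE; adjusted p = 0.167, 0.298 and 0.257). Both space flight values lay below both ground control values for these 3 genes and for Csf1r, and above both for Spi1, H2-Ab1 and Cd74. Of all measured genes, 45.5% were separated in 1 of these 2 ways, where chance gives 33.3%. Csf1r and Cd68 were among the brightest genes, at 15.26 and 15.27 in ground control where the highest normalized value of any probe set was 16.0. With the mean of its 3 probe sets, Csf1r stood at −0.84 (adjusted p = 0.106). Spi1, the lineage factor of myeloid cells, stood at 0.44 ± 0.25 and the co-receptor Cd14 at 0.13 ± 0.25. Of the class II antigen presentation genes, Cd74 stood at 0.95 ± 0.28 (SE; adjusted p = 0.169), H2-Ab1 at 0.46 ± 0.28 and H2-Aa at 0.14 ± 0.28, with probe sets of H2-Aa disagreeing in sign. With each array shifted to 1 median, the median of all genes moved to −0.16, and Cd14 and H2-Aa, at −0.11 and −0.11, stayed above it. The proliferation marker Mki67 stood at 0.70 ± 0.44, with 8.34 and 9.71 on the space flight arrays.

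The list of neutrophil and granulocyte markers stood highest of the 34 lists tested, with a median difference of 1.36 over 17 measured genes (camera adjusted p = 1.47e-11; adjusted p = 0.628 with an estimated correlation). Over all genes 2 members rose and 0 fell; adjusted over the list alone, 12 were higher, 1 was lower and 4 did not pass. The 12 included the secondary granule genes Camp, Ngp, Ltf and Lcn2 (2.07 ± 0.35, SE), the primary granule genes Mpo (1.42 ± 0.36), Elane (1.72 ± 0.49) and Prtn3 (1.63 ± 0.33), and S100a8 and S100a9 (1.36 ± 0.27, and 0.87 without space flight replicate 2). The collagenase gene Mmp8 was the lower one, at −0.64 ± 0.22 and −0.38 without space flight replicate 2, and the receptor gene Csf3r stood at 0.05 ± 0.40. Stfa3, also among the 12, belongs to a family of near-identical copies and had a ground control mean of 5.07, below the dim limit. The list's mean was 0.94 on space flight array 1 and 1.45 on array 2, the array with the Gapdh ratio of 15.2.

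Erythroid markers stood higher as well, with a median of 0.80 over 15 measured genes (camera adjusted p = 0.00152; adjusted p = 0.628 with an estimated correlation) and means of 0.68 and 1.05 on space flight arrays 1 and 2. The ground control mean reached the dim limit for 11 of the 15, and the others were measured only through their higher space flight values. The filter on dim genes thus favoured a higher list, and with no such filter the list's mean was 0.93. Over all genes 0 members passed limma's test, with 5 at an unadjusted p under 0.05; adjusted over the list alone, 4 were higher, 0 were lower and 11 did not pass. The 4 were the red cell anion exchanger Slc4a1 at 2.17 ± 0.43 (SE) and 0.88 on another measured probe set, the haem synthesis enzyme Alas2 at 1.23 ± 0.38, Hemgn at 1.54 ± 0.50, which fell to 0.88 without space flight replicate 2, and the erythroid transcription factor Klf1 at 1.36 ± 0.45. The probe set used for Slc4a1 is of the class that can also bind other transcripts, and one below the dim limit gave −1.30. Hemgn and Klf1 had ground control means of 6.71 and 6.61, close to the dim limit of 6.40. The transferrin receptor gene Tfrc stood at −0.14 ± 0.24, and at −0.66 and −2.14 on its 2 other probe sets.

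Genes of cell cycle arrest and p53 response stood higher, with a median of 0.51 over 22 genes (camera adjusted p = 0.000502; adjusted p = 0.628 with an estimated correlation). Taken over all genes, 0 members passed limma's test, with 8 at an unadjusted p under 0.05; adjusted over the list alone, 7 were higher, 1 was lower and 14 did not pass. Bbc3, the cell cycle inhibitor Cdkn1a (1.37 ± 0.23, SE), Btg2 (1.60 ± 0.35) and Gadd45b (1.56 ± 0.35, and 0.99 without ground control replicate 1) led the 7, and Cdkn1c stood lower at −0.44 ± 0.14, and at −0.26 without space flight replicate 1. The list's means were 0.81 and 0.49 on space flight arrays 1 and 2. With any 1 array left out, this list and those of neutrophil and erythroid markers were still called.

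Immediate early genes, which cells transcribe within minutes of a stimulus, had a median of 0.39 over 18 genes (camera adjusted p = 0.0169; adjusted p = 0.634 with an estimated correlation). Of these, 0 passed limma's test over all genes, with 6 at an unadjusted p under 0.05; adjusted over the list alone, Nr4a1 (2.33 ± 0.48, SE), Egr1 (1.33 ± 0.38), Jund (0.96 ± 0.29) and Junb (0.99 ± 0.31) were higher, 0 were lower and 14 did not pass. The ground control mean of Nr4a1, 6.13, lay below the dim limit. Without space flight replicate 1 Egr1 stood at 0.84, and without space flight replicate 2 Jund stood at 0.51. The list's means were 0.61 and 0.27 on the space flight arrays, and it was not called without space flight replicate 1 (adjusted p = 0.252) or without an intensity trend (adjusted p = 0.0615).

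S phase and DNA replication genes had a median of 0.32 over 25 genes (camera adjusted p = 0.0169; adjusted p = 0.634 with an estimated correlation). Limma's test over all genes passed 0 of them, with 6 at an unadjusted p under 0.05; adjusted over the list alone, the replication helicase genes Mcm7 (1.45 ± 0.37, SE) and Mcm4 (1.09 ± 0.30), Slbp (1.12 ± 0.29) and Rrm2 (1.52 ± 0.42) were higher, 0 were lower and 21 did not pass. Another measured probe set of Mcm4 gave 0.0081 and one of Slbp gave 0.03. The probe sets used for Mcm4 and Rrm2 are of the class that can also bind other transcripts. Others of Rrm2, below the dim limit, gave 0.38 and 0.48, while others of Mcm7 gave 1.48, 1.54 and 1.57. Mcm7 stood at 0.93 without ground control replicate 1 and Rrm2 at 1.01 without space flight replicate 2. The means were 0.40 and 0.33 on the space flight arrays. The list was not called without space flight replicate 1 (adjusted p = 0.0821) or ground control replicate 1 (adjusted p = 0.0760).

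Heat shock and protein folding genes had a median of 0.21 over 20 genes (camera adjusted p = 0.0423; adjusted p = 0.634 with an estimated correlation). Taken over all genes, 0 members passed limma's test, with 4 at an unadjusted p under 0.05; adjusted over the list alone, 2 were higher, 0 were lower and 18 did not pass. The 2 were Hspa1b (2.33 ± 0.40, SE) and Hspa1a (1.55 ± 0.30), inducible chaperones and near-identical copies; Stip1 stood at 0.72 ± 0.30 and Hspb1 at 0.57 ± 0.40. The means were 0.43 and 0.23 on the space flight arrays, and the list was not called without space flight replicate 1 (adjusted p = 0.286) or ground control replicate 2 (adjusted p = 0.0998), nor under cyclic loess (adjusted p = 0.0575) or a shift to 1 median (adjusted p = 0.106).

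Inflammatory cytokines and NF-kB targets had a median of 0.18 over 25 genes (camera adjusted p = 0.0423; adjusted p = 0.634 with an estimated correlation). Of these, 0 passed limma's test over all genes, with 9 at an unadjusted p under 0.05; adjusted over the list alone, 5 were higher, 1 was lower and 19 did not pass. Nfkbiz, the acute phase gene Saa3 (1.34 ± 0.22, SE), Ier3 (0.92 ± 0.18) and the neutrophil chemokine genes Cxcl2 (0.97 ± 0.25) and Cxcl3 (2.05 ± 0.53, and 1.36 without ground control replicate 1) were the 5, and Tnfaip2 was the lower one at −0.67 ± 0.17. The means were 0.26 and 0.43 on the space flight arrays, and the list was not called without space flight replicate 2 (adjusted p = 0.169) or ground control replicate 1 (mean 0.22, adjusted p = 0.124), nor under the 3 other array scalings (adjusted p from 0.0514 to 0.0667).

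Macrophage differentiation and identity genes stood lower, with a median of −0.18 over 27 genes (camera adjusted p = 0.0205; adjusted p = 0.634 with an estimated correlation). Limma's test over all genes passed 0 of them, with 11 at an unadjusted p under 0.05; adjusted over the list alone, 5 were lower, 2 were higher and 20 did not pass. The Fc receptor gene Fcgr3, the beta-glucan receptor gene Clec7a (−0.74 ± 0.20, SE), the mannose receptor gene Mrc1 (−1.47 ± 0.43, and −0.92 without space flight replicate 1), Cd68 and Csf1r were the lower ones. The transcription factor gene Cebpb (1.12 ± 0.21) and the complement gene C1qb (1.42 ± 0.40) were higher, and the abundant lysozyme gene Lyz2 stood at −0.06 ± 0.11. The list's means were −0.22 and −0.07 on the space flight arrays. It was not called without space flight replicate 1 (mean −0.07, adjusted p = 0.183) or ground control replicate 2 (mean −0.04, adjusted p = 0.181), and its mean was −0.25 without ground control replicate 1. Under the 3 other array scalings it was not called either (adjusted p from 0.0601 to 0.266), nor with no filter on dim genes (mean −0.029, adjusted p = 0.0827).

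Lysosome and phagocytosis genes stood lower, with a median of −0.04 and a mean of −0.23 over 23 genes (camera adjusted p = 0.0169; adjusted p = 0.628 with an estimated correlation). Taken over all genes, 0 members passed limma's test, with 5 at an unadjusted p under 0.05; adjusted over the list alone, 5 were lower, 0 were higher and 18 did not pass. The 5 were Asah1, the cholesterol transporter Npc1 (−1.28 ± 0.24, SE), the proton pump subunit Atp6v0d2 (−1.15 ± 0.22), the collagen-degrading protease Ctsk (−1.02 ± 0.20) and Gusb (−0.73 ± 0.16). Other lysosomal genes stood near 0, among them Lamp1 at −0.01 ± 0.11 and Ctsd at 0.05 ± 0.11. The means were −0.21 and −0.25 on the space flight arrays, and the list was not called without space flight replicate 2 (mean −0.21). It was not called under the 3 other array scalings either (camera adjusted p from 0.171 to 0.559). Its mean was −0.064 with values as deposited and −0.16 with cyclic loess. After a shift to 1 median it was −0.27, where the median of all genes was −0.16.

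Lipid efflux and lipid droplet genes had a median of −0.30 over 17 genes (camera adjusted p = 0.0423; adjusted p = 0.628 with an estimated correlation). This was the 1 list that fry called (adjusted p = 0.0280). Of its members, 0 passed limma's test over all genes, with 8 at an unadjusted p under 0.05; adjusted over the list alone, the nuclear receptor gene Pparg (−1.79 ± 0.42, SE), the desaturase gene Scd2 (−0.90 ± 0.21) and the fatty acid oxidation gene Cpt1a (−0.82 ± 0.26) were lower, Fabp4 (1.03 ± 0.29, and 0.65 without ground control replicate 1) and Ppard (1.32 ± 0.38) were higher, and 12 did not pass. Probe sets of Scd2, Cpt1a and Fabp4 disagreed in sign, and Cd36 stood at −0.35 ± 0.13. Actin cytoskeleton and focal adhesion genes had a median of −0.17 over 29 genes (camera adjusted p = 0.0395; adjusted p = 0.628 with an estimated correlation), and 0 members passed limma's test over all genes or adjusted over the list alone, with 6 at an unadjusted p under 0.05. Its leading members in the direction of the call were Itgb2 at −0.59 ± 0.18, Itga5 at −1.23 ± 0.38, Vim at −0.37 ± 0.12 and Lcp1, whose probe sets disagreed in sign, at −0.38 ± 0.16. With 1 array left out, Itgb2 ran from −0.80 to −0.38 and Vim from −0.50 to −0.24. Other measured probe sets of Itga5 gave −0.05 and −0.10, and others of Vim −0.04 and −0.21. Pfn1, the member with the smallest p, stood above 0 at 1.24 ± 0.32, as did Itgb1 at 0.84 ± 0.28; both were named after their values were seen. On space flight arrays 1 and 2 the lipid list had means of −0.25 and −0.25 and the actin list −0.08 and −0.17. Neither was called with any 1 array left out: adjusted p ran from 0.0760 without ground control replicate 1 to 0.183 without space flight replicate 1 for the lipid list, and from 0.0536 without ground control replicate 1 to 0.332 without space flight replicate 2 for the actin list. Under the 3 other array scalings adjusted p ran from 0.139 to 0.262 for the lipid list and from 0.139 to 0.559 for the actin list, which had 0.498 with the mean of probe sets.

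**Figure D3:**
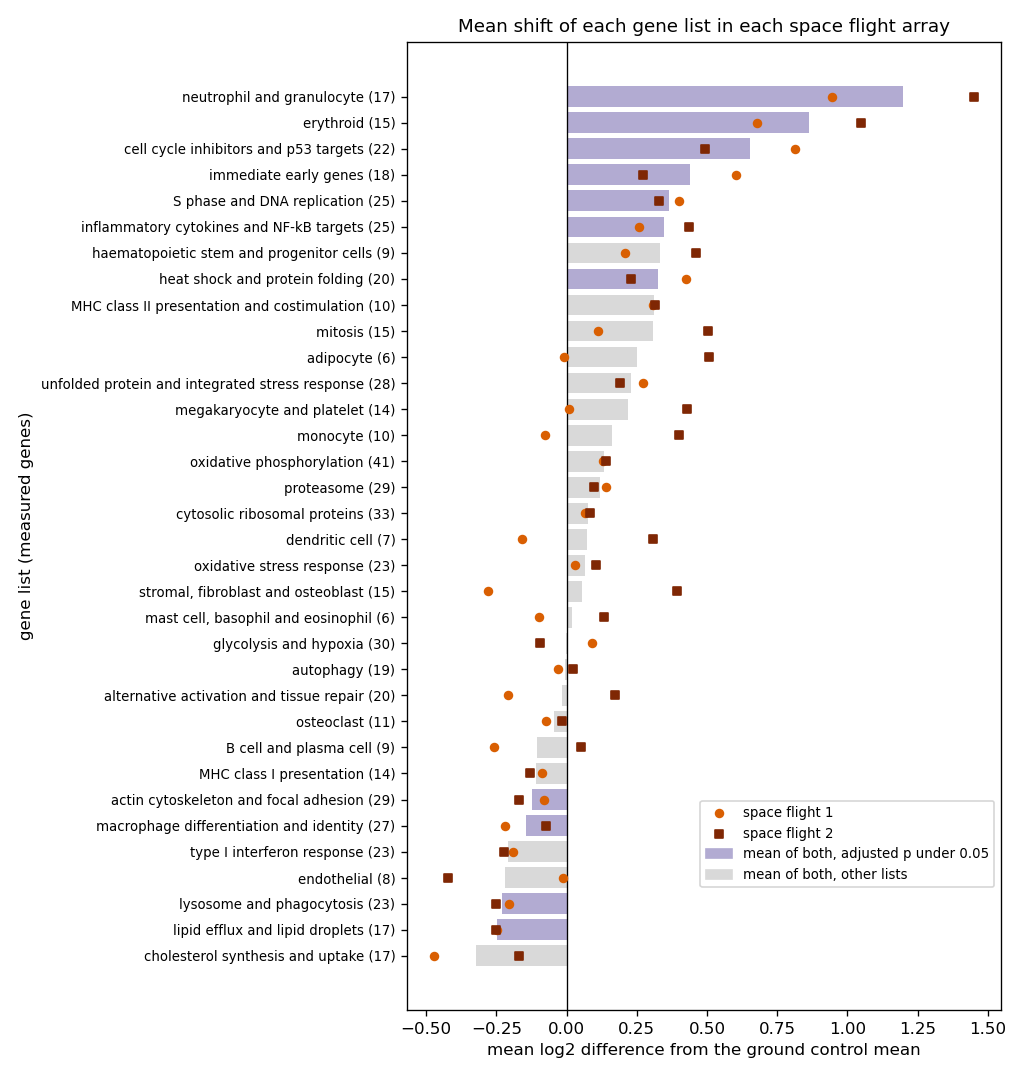
Bars give the mean log2 difference of each of the 34 gene lists from the ground control mean, purple where the adjusted p was under 0.05, and points give the mean on each space flight array. Neutrophil and granulocyte markers lie farthest above 0, at 0.94 and 1.45, and lipid efflux genes at −0.25 and −0.25.

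Of the 34 lists, camera called 7 higher and 4 lower; the split was 8 and 1 with values as deposited, 5 and 0 with cyclic loess and 6 and 0 with each array shifted to 1 median. The other 23 lists were not called. Closest to the threshold were the unfolded protein and integrated stress response (adjusted p = 0.0583), oxidative phosphorylation (adjusted p = 0.0677) and cholesterol synthesis and uptake (adjusted p = 0.0812). Class II presentation (adjusted p = 0.193), mitosis (adjusted p = 0.232), osteoclast markers (adjusted p = 0.232), the type I interferon response (adjusted p = 0.349), adipocyte markers (adjusted p = 0.364), stem and progenitor cell markers (adjusted p = 0.364) and the proteasome (adjusted p = 0.383) followed. Endothelial and B cell markers, class I presentation and cytosolic ribosomal proteins each had an adjusted p of 0.450. Megakaryocyte markers had 0.611, dendritic cell markers and alternative activation 0.824, the oxidative stress response 0.826, monocyte markers 0.973, glycolysis, stromal markers and autophagy 0.978, and mast cell markers 0.988. Of these 23 lists, 11 had 0 members passing when adjusted over the list alone. Higher and lower members adjusted over the list alone numbered 9 and 1 for the unfolded protein list, 2 and 1 for oxidative phosphorylation, 1 and 6 for cholesterol synthesis, 1 and 2 for osteoclast markers, 2 and 1 for adipocyte markers and 4 and 4 for the proteasome. They numbered 0 and 1 for ribosomal proteins, 2 and 4 for alternative activation, 2 and 2 for oxidative stress, 2 and 1 for monocyte markers, 0 and 1 for stromal markers and 1 and 1 for autophagy. Over all genes only Igf1, a member of the alternative activation list, passed in these 23 lists. For monocyte and stromal markers the median (−0.23 and −0.03) and the mean (0.16 and 0.06) differed in sign, and camera's direction was up. The list of T cell and NK cell markers had 4 measured genes and was not tested; they were Cd5 at −0.78, Cd8a at −0.92, Il7r at −0.50 and Nkg7 at 0.91.

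The brightest markers of other cell types gave no gene that passed over all genes. Monocyte F13a1 stood at −0.65 ± 0.20 (SE), and at −0.42 without space flight replicate 1, and Spn at −0.37 ± 0.32, osteoclast Tcirg1 at −0.37 ± 0.19, B lineage Blnk at −0.58 ± 0.30 and Sdc1 at 0.19 ± 0.27, stromal Pdgfra at −1.55 ± 0.40, with −0.63 on another measured probe set, and Acta2 at −0.03 ± 0.23. Progenitor Lmo2 and Tal1 stood at −0.32 ± 0.34 and 0.36 ± 0.33, dendritic cell Id2 and Cd83 at 0.11 ± 0.15 and −0.15 ± 0.30, and megakaryocyte Pf4 and Itgb3 at −0.04 ± 0.19 and −0.39 ± 0.22. Mast cell Gata2 and Il3ra stood at −0.38 ± 0.37 and 0.26 ± 0.48, adipocyte Pnpla2 at 0.21 ± 0.23, and endothelial Esam and Vwf at 0.24 ± 0.28 and −0.29 ± 0.25. Probe sets of Spn, Sdc1, Id2 and Itgb3 disagreed in sign.

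All 7 gene calls ended, with the sign of each difference kept, under a shift of each array to 1 median, without the filter on dim genes, with the mean of a gene's probe sets, and without an intensity trend in the variance. Without the trend, the lists of heat shock, inflammatory, lysosome, macrophage, actin and lipid genes were not called either (adjusted p from 0.133 to 0.172). None of the 11 list calls held with an estimated correlation (adjusted p from 0.628 to 0.634). That estimate rests on 2 residual degrees of freedom and left little power. The lowest camera adjusted p of all 34 lists was 0.628 there. A miss therefore does not separate correlated members from lack of power, and the calls rest on the preset correlation.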

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

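Of the tests in this part, all were set before their results were seen except those of degraded RNA, which were chosen after. Control probe sets outside the comparison drew attention on 1 array. On space flight replicate 2 the Gapdh 3' to 5' ratio was 15.2 against at most 4.13 in ground control, and its spike-in signal relative to the ground control mean was 2.29 against at most 1.01.

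Space flight replicate 2 stood farther from the ground control mean than replicate 1 did, with an SD over genes of 0.692 against 0.609. If its RNA were more fragmented, probe sets of 1 gene would scatter more on it: the median spread within 2344 genes was 1.13 times that of replicate 1 (0.303 against 0.269), above the ratio of 1.1 set for excluding this explanation and below the one set for keeping it. If its signal were weak, dim genes alone would scatter: the SD ratio of replicate 2 to replicate 1 was 1.01 in the brightest of 4 equal bins of genes, as weak signal would need, but 1.28 in the dimmest, short of the 1.3 it was set to reach. Its spike-in signal of 2.29, on arrays scaled to 1 trimmed mean, goes with weak sample signal if each array received equal spike amounts. Both explanations may hold and cannot be told apart with 1 such array. No biological explanation of this difference between replicates was tested.

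Neutrophil markers were higher in space flight, with a mean difference of 1.20 over 17 genes (camera adjusted p = 1.47e-11; adjusted p = 0.628 with an estimated correlation). Degraded RNA on space flight replicate 2 as the whole source is argued against by the mean without that array, 0.94, which rests on space flight array 1 alone. Over the main and the 3 other scalings the median of all genes ran only from −0.16 to 0.041. A shift of that size could not remove a mean of 1.20, so array scaling was not put to a strict test. The lowest mean under the 3 other scalings, 1.04, shows only that the choice among them did not make the difference. More cells of the granulocyte lineage in the flown cultures and higher expression per cell both stay open, and no test here separates them; Csf3r stood at 0.05 and Mmp8 at −0.64, or −0.38 without space flight replicate 2.

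Erythroid markers were higher as well, with a mean difference of 0.86 over 15 genes (camera adjusted p = 0.00152; adjusted p = 0.628 with an estimated correlation). Degraded RNA on space flight replicate 2 as the whole source is argued against by a mean of 0.68 without that array, which rests on space flight array 1 alone. The lowest mean under the 3 other scalings was 0.76. Those scalings moved all genes too little to test array scaling strictly, so this shows only that the choice among them did not make the difference. The 4 probe sets shared by globin copies, which name no single gene, stood at 14.79, 14.14 and 11.46 in space flight against 13.42, 12.45 and 9.07 in ground control for alpha-globin, and at 12.97 against 10.73 for beta-globin, in normalized log2 signal. Dimmer probe sets that name 1 globin gene were mixed. On space flight arrays 1 and 2, Hbb-b2 had 8.15 and 9.26 against 8.21 and 8.09 in ground control. On its other probe set it had 7.70 and 8.60 against 5.48 and 6.42. Hba-a1 had 6.84 and 7.26 against 6.76 and 6.25. Hba-a2, below the dim limit, was lower, at 4.50 and 4.39 against 5.62 and 5.51. Red cells had been lysed in the marrow before it was cultured, per the labels' protocols, and whether more erythroid cells or higher expression per cell lay behind these values was not tested. Tfrc stood at −0.14 and Gata1 at −0.42.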

How the results depend on the processing

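All alternatives in this part were set before the data were examined. Values are numbers of genes or lists called, or log2 differences, space flight minus ground control. The counts of 5 higher and 2 lower genes became 12 and 4 with values as deposited, 16 and 5 with cyclic loess, 6 and 6 with a pseudocount of 64, 16 and 12 with the dim limit at the 75th percentile (6920 genes tested), 10 and 1 with every probe set on its own, and 53 and 47 at an adjusted p under 0.10. A pseudocount of 1 and a log2 difference of at least 1 gave 5 and 2, and robust variances 5 and 3. In limma, 0 and 0 genes passed after a median shift (1489 at an unadjusted p under 0.05), with no filter on dim genes (1942, of 18193 tested), with the mean of probe sets (1307) and with no intensity trend (1349). The median shift moved the median of all genes to −0.16, and that common shift is part of each value under it. With the replicate block 220 and 213 genes passed; across genes the difference between replicates 1 and 2 in space flight correlated at 0.0572 with that in ground control, and the 2 pairs are too few to show that the numbers pair the arrays.

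Leaving out 1 array gave 6 to 470 higher and 1 to 610 lower genes, and the lone array is then assumed to vary like the other group. The median SD over genes was 0.333 with all arrays, 0.271 and 0.272 without space flight replicate 1 and 2, and 0.423 without either ground control replicate. Of the 7 passing genes, Ngp missed the threshold with values as deposited (adjusted p = 0.0513), and H3c11, Camp, Ngp and Mamdc2 missed it with every probe set (adjusted p from 0.0557 to 0.0614), as did Mamdc2 without ground control replicate 1 (adjusted p = 0.0886). H3c11 had no value with the 75th percentile limit. Over the alternatives the passing genes were called 77 times and missed 34 times, and none turned direction; elsewhere the cause was not tested.

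For the lists, 7 higher and 4 lower became 8 and 1 with values as deposited, 5 and 0 with cyclic loess, 6 and 0 after the median shift, 4 and 0 with no intensity trend, 9 and 5 with the replicate block, 0 and 0 with an estimated correlation and 0 and 1 by fry. Leaving out 1 array gave 4 to 7 higher and 1 to 2 lower. Neutrophil markers and p53 targets were called in all 14 alternatives that keep camera's preset correlation, and erythroid markers in all 13 that gave it a value, the 75th percentile limit leaving under 5 genes. Immediate early and S phase genes were called in 12 of 14, heat shock and lysosome in 9, macrophage and inflammatory genes in 7, lipid efflux in 5 and actin in 4, each in 1 direction throughout. Camera has no robust option, lists were not tested with every probe set, and the ribosomal background was not run because ribosomal proteins were not called.

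Among results not called, 14 genes and 11 lists turned direction somewhere. After the median shift Cd14, H2-Aa, Sdc1 and Pnpla2 stayed above the median of all genes, so the common shift turned them, and Pnpla2 turned in no other alternative; elsewhere the cause was not tested. A list's direction comes from camera, so its mean can keep its sign. After the median shift Cd14 was at −0.11, H2-Aa −0.11, Sdc1 −0.064, Pnpla2 −0.028, alternative activation −0.19 and glycolysis −0.13. With the mean of probe sets Cpt1a was at 0.014, Id2 −0.15, Acta2 0.46, Fabp4 −0.48, alternative activation 0.065, autophagy 0.017, dendritic cells −0.024, glycolysis 0.029 and mast cells −0.17. With no filter, alternative activation was at 0.090, B cells 0.18, dendritic cells −0.040, stem and progenitor cells −0.042 and stromal −0.0060. With no intensity trend, alternative activation was at −0.017, mast cells 0.018 and stromal 0.056, and by fry mast cells were at 0.018 and stromal at 0.056. With the 75th percentile limit, autophagy was at −0.0039, glycolysis 0.0028 and monocytes 0.062. Glycolysis was at 0.068 as deposited, and with loess glycolysis was at 0.026, mast cells 0.028 and stromal 0.039.

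With 1 array left out, the ranges of those that turned were −0.24 to 0.50 for Cd14, −0.18 to 0.47 for H2-Aa, −0.78 to 0.14 for Lmo2, −0.025 to 0.24 for Id2, −0.45 to 0.16 for Cd83, −0.018 to 0.40 for Sdc1, −0.46 to 0.17 for Tfrc, −0.10 to 0.031 for Pf4, −0.42 to 0.94 for Il3ra, −0.15 to 0.083 for Acta2 and −0.18 to 0.67 for Esam. For lists they were −0.21 to 0.17 for alternative activation, −0.030 to 0.022 for autophagy, −0.16 to 0.31 for dendritic cells, −0.095 to 0.091 for glycolysis, −0.10 to 0.14 for mast cells, 0.0081 to 0.43 for megakaryocytes, −0.077 to 0.40 for monocytes, −0.023 to 0.16 for oxidative stress and −0.28 to 0.39 for stromal markers.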

Other observations

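The families of gene symbols described in this part were chosen after the data had been seen; the gene lists were not. The list of the unfolded protein and integrated stress response was not called (camera adjusted p = 0.0583; adjusted p = 0.628 with an estimated correlation). Over all genes 0 of its 28 members passed limma's test and 11 had an unadjusted p under 0.05; adjusted over the list alone, 9 were higher, 1 was lower and 18 did not pass. The 9 included the transcription factor genes Atf4 (0.74 ± 0.15, SE) and Ddit3 (1.05 ± 0.22), the phosphatase subunit gene Ppp1r15a (1.36 ± 0.27), Trib3 (1.04 ± 0.23) and Ddit4 (1.62 ± 0.34), and Herpud1 was the lower one at −0.85 ± 0.28. Among the 18 were Atf3 at −0.12, Asns at 0.11, Chac1 at 0.22, Slc3a2 at −0.03, Slc7a11 at −0.67, Vldlr at 0.04, Shmt2 at 0.15 and the endoplasmic reticulum chaperone gene Hspa5 at −0.12. The list was called without space flight replicate 2 (adjusted p = 0.0294) and ground control replicate 1 (adjusted p = 0.0175) and not without space flight replicate 1 (adjusted p = 0.252), and over all its alternatives adjusted p ran from 0.0175 to 0.628.

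The list of cholesterol synthesis and uptake was not called either (camera adjusted p = 0.0812; adjusted p = 0.634 with an estimated correlation). Limma's test over all genes passed 0 of its 17 members, with 9 at an unadjusted p under 0.05; adjusted over the list alone, 6 were lower, 1 was higher and 10 did not pass. The lower ones included the enzyme genes Sqle (−1.11 ± 0.22, SE), Msmo1 (−0.92 ± 0.23), Nsdhl (−1.26 ± 0.35) and Fdps (−1.41 ± 0.47, and −0.73 without space flight replicate 2), and the higher one was Cyp51 at 0.95 ± 0.27. The 10 were Srebf2 at 0.92, Insig1 at 0.62, Mvd at 0.45, Hmgcs1 at 0.21, Sc5d at 0.03, Fdft1 at 0.01, Dhcr7 at −0.16, Idi1 at −0.29, Mvk at −0.54 and Stard4 at −0.84. The list's means were −0.47 and −0.17 on space flight arrays 1 and 2, and it was called without space flight replicate 2 (adjusted p = 0.00981) and not without space flight replicate 1 (adjusted p = 0.338), in a range over its alternatives from 0.00981 to 0.634. Of the alternative activation list, Mrc1 (−1.47, and −0.92 without space flight replicate 1), Timp2 (−0.95 ± 0.23) and the matrix gene Thbs1 (−1.46 ± 0.41) lay below 0 with Igf1, while Mmp9 (1.73 ± 0.40) and Chil3 (1.28 ± 0.23), the latter also a neutrophil marker here, lay above.

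A scan of all 179 families of genes that share the letters of their symbol and have at least 8 measured genes found 0 that camera called, with 22 at an unadjusted p under 0.05. The lowest adjusted p, 0.0639, was that of the respiratory complex I families Ndufb (mean 0.38 over 10 genes) and Ndufa (mean 0.35 over 13), followed by the small nucleolar RNA host genes Snhg (mean 0.51 over 11, adjusted p = 0.0658) and the mitochondrial ribosomal genes Mrpl (mean 0.23 over 47, adjusted p = 0.0744). With an estimated correlation each of these 4 had an adjusted p of 0.992. Adjusted p of each changed with the space flight array left out. For Ndufb, Ndufa and Mrpl it was lower without replicate 1 than without replicate 2, the array with the Gapdh ratio of 15.2. For Snhg it was the other way round. The lone array is then assumed to vary like the other group, and family means per array were not computed. Whether these shifts came from 1 array was therefore not tested.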
